A study of Mus musculus with 8 samples.

How the data were processed

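Uterine cryosections of 10 µm from 4 WT and 4 Ezh2cKO mice were placed on Visium slides, fixed, stained and made into spatial libraries, per the labels' protocols. The genome build was GRCm38, per the submitters' processing notes. The aligner, the way spots were named epithelium or stroma, and the test behind the p-values are not given in the sources used here. Genes that guided the naming of spots, if any, would be no finding between compartments.

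The 4 deposited tables hold, per the file headers, an average per group, a log2 fold change for each group against the other and an adjusted p-value (FDR). The deposited averages are pooled over the animals of a genotype, so there is 1 value per gene and group, with no spread between animals and no replicate check. The authors' adjusted p-values may measure the spread between spots and not between animals. Every listed gene has an average above 1 in at least 1 group, and the lowest of these larger averages ranged from 1.00 to 1.01 over the tables. A low-level gene is thus listed more readily when it is high in 1 group, which favours a large fold, and list members above 1 in the lower group were looked at on their own, after the data were seen.

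Pooled UMI sums were recovered from the deposited values. The deposited log2 fold change equals the log2 ratio of both groups' pooled sums plus 1, each divided by the group's size factor sum plus 1, and the size factor sums were solved by least squares. With these sums, the average times its size factor sum was within 0.01 of a whole number for 100% of genes in every table. A group's recovered sums differed between its tables for 0 genes. Folds given in the text are ratios of the recovered sums scaled by the size factor sums, without a pseudocount. Their 95% intervals are exact Clopper-Pearson intervals of the recovered UMIs and cover counting error only. Genes were called where the authors' deposited adjusted p-value was under 0.05, and no p-value of a single gene was computed. On simulated tables with 200 changed genes, 100% of sums were recovered. For KO against WT epithelium (5811 genes), intervals covered the set value for 96.3% of unchanged genes, 92% of 2-fold and 96% of 4-fold changes. For WT epithelium against WT stroma (1769 genes) the shares were 95.0%, 92% and 90%, for KO against WT stroma (1191 genes) 95.4%, 96% and 96%, and for KO epithelium against KO stroma (2744 genes) 95.8%, 98% and 100%.

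Before the data were examined, 30 gene lists, the comparisons, the alternatives and a naming rule were fixed. The rule took, per table, up to 10 called genes per direction with the largest log2 fold among those at or above the median level of called genes, leaving out unnamed gene models. It also took Ezh2, Pgr and Esr1, up to 4 called members per direction of a list with at least 3 called members or with a gene already named, and up to 5 genes per direction pair called in both tables of an overlap. Called genes that the text names outside the rule are said to be so. Each list was tested by 2-sided Fisher exact tests of its called-higher and its called-lower members against the other genes of the table, with Benjamini-Hochberg adjustment over 238 tests. Genes are not independent replicates, and these tests describe the called sets. List medians were compared with 10000 random lists of the same size matched on mean level, a step added after the data were seen. The draws ignore that genes of a list vary together, so their percentiles are no test between animals.

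Alternatives fixed in advance were an adjusted p-value threshold of 0.01, a minimum absolute log2 fold of 1, and leaving out the lowest 25% of genes by level. Centring the folds on the median gene was added after the data were seen. The planned test of the difference of genotype effects between compartments, the recomputed adjustment and counts adjusted over the list alone need raw p-values or standard errors and were not run. The planned additivity check over 1167 genes in all 4 tables gave a median absolute difference of 0.00154 in the deposited log2 values. This follows from their shared sums and tests nothing further.

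Of 5828 gene IDs, 5826 were found in GENCODE release M21, which is on GRCm38 and gave the gene positions. Scripts in Python used NumPy, SciPy, pandas and matplotlib.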

Results

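The series profiled uteri of ovariectomized adult mice by Visium, an array method in which barcoded spots under a tissue section capture messenger RNA so that each transcript keeps its position. Each spot is a small region that can hold several cells. The 8 uteri came from 4 wild-type (WT) females and 4 Ezh2cKO females (KO below), whose floxed Ezh2 alleles are paired with a Cre driven from the progesterone receptor locus. Ezh2 encodes the methyltransferase of Polycomb repressive complex 2, which places the repressive mark H3K27me3. Uteri were taken at postnatal day 112 ± 11, after ovariectomy at day 71 ± 4, so that ovarian hormones were withdrawn. The authors' tables compare spots they named epithelium or stroma, pooled over the animals of a genotype. Across all listed genes the recovered UMI totals were 1552958 in KO epithelium, 1428541 in WT epithelium, 947663 in KO stroma and 416747 in WT stroma. These totals run over all genes listed for a group, which differ between groups. On the common scale of the size factors, the KO stroma pool was 2.01 times as deep as the WT stroma pool and the KO epithelium pool 1.08 times as deep as the WT epithelium pool.

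The first question was which transcripts differ in the uterine epithelium when Ezh2 is deleted. Of 5811 listed genes, 7 were called, 4 higher and 3 lower in KO. Asb4, a substrate adaptor of a ubiquitin ligase, rose 6.74-fold (95% counting interval 4.34 to 10.9), from 23 UMIs in WT to 168 in KO. Igfbp5, a secreted binding protein of insulin-like growth factors, rose 3.13-fold (2.61 to 3.78) in these spots. It is also a gene of the stroma, called higher in stroma than in epithelium by 5.99-fold in WT and 2.86-fold in KO. Dio2, the deiodinase that activates thyroid hormone, rose 2.88-fold (2.36 to 3.53), and the chemokine Cxcl14 rose 2.72-fold (2.47 to 3.01). Mt3, a metallothionein, fell 4.38-fold (2.85 to 6.94), the cytosolic sulfotransferase Sult1d1 fell 4.09-fold (3.26 to 5.17), and Lcn2, an iron-binding defence protein that responds to estrogen in the uterus, fell 3.30-fold (2.58 to 4.27).

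In the authors' deposited table the adjusted p was 6.71e-05 for Asb4, 0.00053 for Sult1d1, 0.0102 for both Mt3 and Cxcl14, 0.0158 for Dio2, and 0.0367 for both Igfbp5 and Lcn2. Asb4, Mt3 and Lcn2 were named after their values were seen, since the naming rule asked for a level at or above the median of the called genes. Ezh2 itself is not among the genes analysed here, so the deletion could not be checked at its own transcript. The Cre driver gene Pgr had a log2 ratio of -0.21 in epithelium (240 UMIs in KO and 257 in WT) and Esr1, the estrogen receptor, had -0.12. The authors' deposited table gives both an adjusted p of 1.

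Few of the gene groups fixed in advance held a called gene in epithelium. Among 31 listed markers of simple uterine epithelium none was called, and their median log2 ratio of KO over WT was -0.20. None of 29 endometrial stroma markers was called either, although 26 had a higher value in KO, with a median of 0.60. Extracellular matrix genes had a median of 0.45 over 33 members with no call. Smooth muscle genes had a median of -0.32 over 18 members. Set against random lists matched on level, the medians of the endometrial stroma and matrix lists lay above 100% of them, that of the simple epithelium list above 0.15% and that of the smooth muscle list above 0.11%. Among smooth muscle genes Acta2, named after its value was seen, was 2.65 times as high in WT (116 against 284 UMIs), with an adjusted p of 1 in the authors' deposited table. None of 11 listed developmental regulators that are textbook targets of the complex was called (median 0.12, above 99.1% of random lists matched on level). No call fell on any of 12 listed Hox genes (median -0.06, which becomes 0.04 once folds are centred on the median gene). The 6 listed basal and stratified squamous genes had no call either (median -0.14). Most members of each of these lists were not among the listed genes, so a change in them could not be seen here. Lcn2 was the one called member among 16 estrogen-responsive genes, 11 of which had a higher value in KO (median 0.23, above 99.99% of random lists), opposite to Lcn2. It was also the one called member among 5 epithelial defence genes, a list that passed its 2-sided Fisher exact test (adjusted p = 0.0409), on that single gene, and lost its call at a threshold of 0.01 (adjusted p = 1). The median gene of the table stood at -0.10, and list medians are to be read against that shift.

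**Figure D1:**
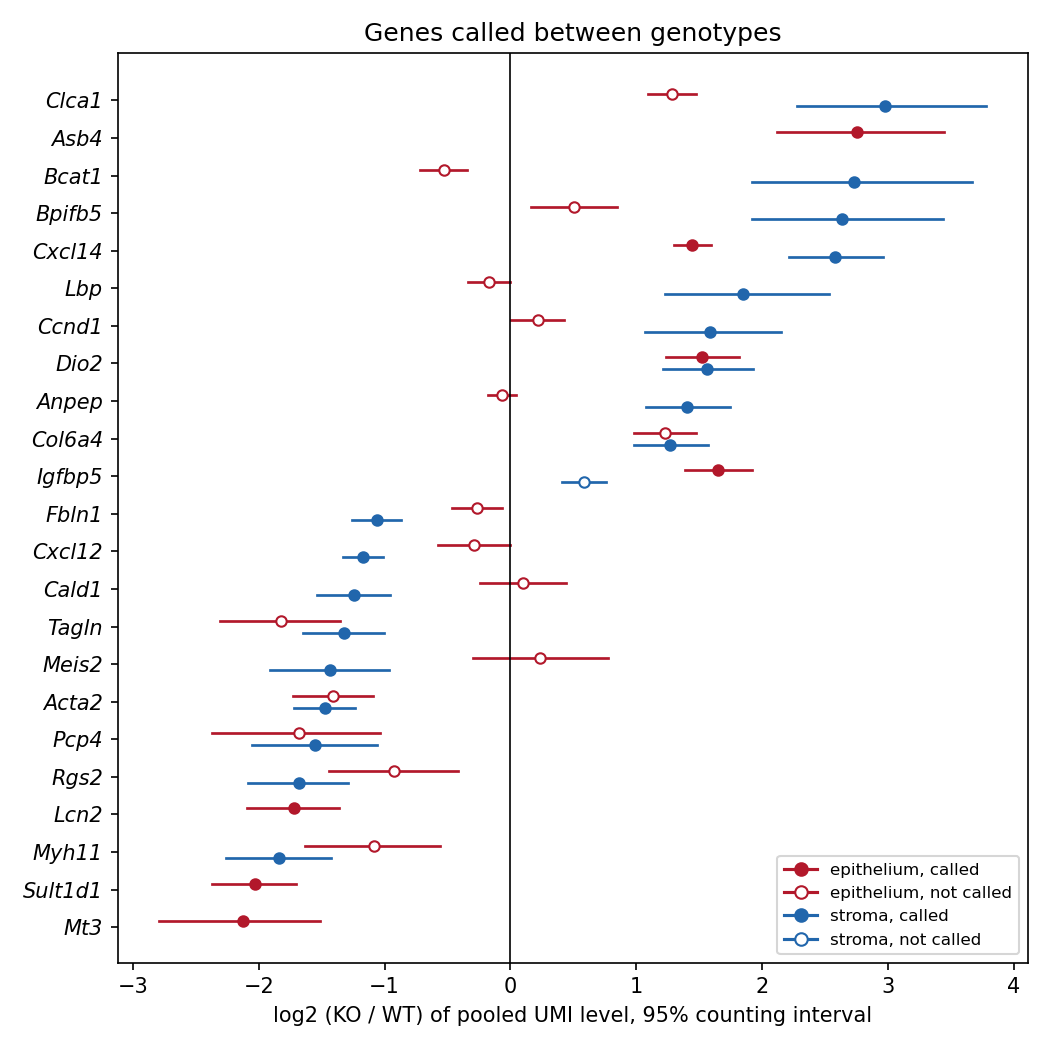
Points give the log2 ratio of KO over WT for every gene called in at least 1 of the genotype comparisons, in epithelium (red) and stroma (blue), and lines give the 95% counting interval. Filled points were called by the authors' adjusted p and open points were not; Cxcl14 and Dio2 are filled and to the right of 0 in both compartments.

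In stroma, 18 of 1191 listed genes were called between genotypes, 9 in each direction. Clca1, a secreted regulator of chloride channels, rose 7.89-fold (95% counting interval 4.84 to 13.8). Bcat1, which starts the breakdown of branched-chain amino acids, rose 6.65-fold (3.79 to 12.8), from 13 UMIs to 174. Bpifb5 rose 6.20-fold (3.78 to 10.8), Cxcl14 5.98-fold (4.65 to 7.81) and Lbp, the lipopolysaccharide-binding protein, 3.60-fold (2.34 to 5.78). The other 4 were Ccnd1, which encodes cyclin D1, at 3.01-fold (2.10 to 4.44), Dio2 at 2.95-fold (2.32 to 3.80), the aminopeptidase gene Anpep at 2.64-fold (2.11 to 3.35) and the collagen gene Col6a4 at 2.41-fold (1.97 to 2.97).

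Smooth muscle genes made up most of the genes that fell in KO stroma. Myh11, the smooth muscle myosin heavy chain, fell 3.58-fold (2.69 to 4.80), Pcp4 fell 2.93-fold (2.08 to 4.16), Acta2, smooth muscle actin, fell 2.78-fold (2.35 to 3.29), Tagln fell 2.51-fold (2.01 to 3.14) and Cald1 fell 2.37-fold (1.95 to 2.90). Myh11, Pcp4, Acta2, Tagln and Cald1 are the 5 called members of the smooth muscle list, whose 14 listed members were all lower in KO, with a median log2 ratio of -0.97. The 8 members with an average above 1 in KO stroma, which WT alone did not bring into the table, were all lower too, with a median of -0.74. The list passed its 2-sided Fisher exact test (adjusted p = 9.85e-07). The other genes that fell were Rgs2, a brake on G protein signalling, at 3.21-fold (2.44 to 4.25), the homeobox gene Meis2 at 2.70-fold (1.95 to 3.77), the chemokine Cxcl12 at 2.25-fold (2.02 to 2.52) and the matrix gene Fbln1 at 2.09-fold (1.83 to 2.39).

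In the authors' deposited table the adjusted p in stroma was 2.94e-05 for Cxcl14, 0.000351 for Rgs2, 0.000403 for Myh11, 0.000466 for Bcat1 and 0.00468 for Clca1, Acta2 and Cald1. Of the 18 genes, Clca1, Bcat1, Bpifb5, Lbp, Ccnd1, Rgs2 and Meis2 were named after their values were seen. Clca1 and Ccnd1 are the called members among 6 estrogen-responsive genes (adjusted p = 0.0137, 2-sided Fisher exact test). The list's call rests on these genes, both called higher in WT epithelium than in WT stroma (Clca1 7.10-fold, Ccnd1 3.80-fold), as the simple epithelium markers are that stood higher in KO stroma. The other 4 were lower in KO and the list's median was -0.23, opposite in sign to the call. The list's call in the Fisher exact test was lost at a threshold of 0.01 (adjusted p = 0.324) and without low-level genes (adjusted p = 1). Fbln1 was the one called gene among 24 endometrial stroma markers, 16 of which had a higher value in KO (median 0.11).

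None of the 9 listed markers of simple uterine epithelium was called in stroma, although all 9 had a higher value in KO, with a median log2 ratio of 1.25. This count depends on the listing, since 7 of the 9 had an average above 1 in KO stroma alone. The 19 markers listed in both compartment tables, where epithelium sets the listing, were all higher in KO stroma than in WT stroma, with a median log2 ratio of 1.14. For examples chosen after their values were seen, Krt8 had 235 UMIs in KO stroma and 44 in WT stroma (2.65-fold, 1.92 to 3.75) and Krt19 had 213 and 36 (2.94-fold, 2.06 to 4.31). The authors' deposited table gives these an adjusted p of 0.107 for Krt8 and 0.112 for Krt19. Pgr had a log2 ratio of -0.13 and Esr1 of -0.35 in stroma.

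**Figure D2:**
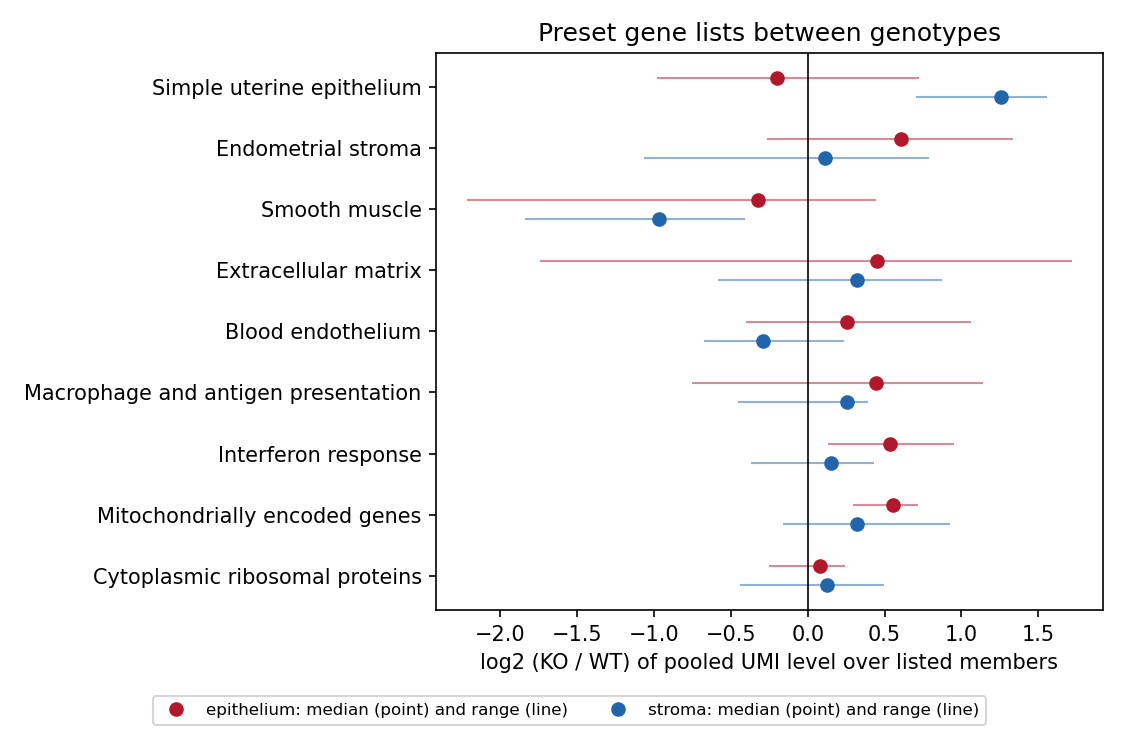
Points give the median log2 ratio of KO over WT across the listed members of 9 preset gene lists, and lines run from the lowest to the highest member, in epithelium (red) and stroma (blue). Simple epithelium markers have a median of 1.25 in stroma and -0.20 in epithelium, and smooth muscle genes have -0.97 and -0.32.

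The genotype comparisons in epithelium and stroma were then set side by side. Cxcl14 and Dio2 were called in both, each higher in KO. Over the 1185 genes listed in both tables, 3 were called in epithelium and 18 in stroma, and independent lists would share 0.0228 genes called higher in both. Both tables use spots of the same 8 uteri, so that independence is not the value to be met with no effect. With 2 shared genes, both of the same sign, the Fisher exact test of sign agreement gave p = 1 and could not have given less. Cxcl14 lies on chromosome 13 (56288643 to 56296551, minus strand) and Dio2 on chromosome 12 (90724552 to 90738438, minus strand) of GRCm38, and both are annotated as protein-coding genes. Whether any gene's genotype effect differed between compartments was not tested, because that test needs a raw p or a standard error.

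In WT uterus the comparison of epithelium with stroma shows how far the spots of each name were separated. Of 1769 listed genes, 509 were called, 231 higher in epithelium and 278 higher in stroma. All 19 listed markers of simple epithelium were called higher in epithelium (adjusted p = 9.75e-16, 2-sided Fisher exact test), with a median log2 ratio of 2.69 and a summed level 6.80-fold higher. Calb1, a calcium-binding protein of luminal epithelium, was 24.5-fold higher (95% counting interval 11.8 to 61.3), and Krt19 was 8.91-fold higher (6.38 to 12.8). Other genes high in epithelium were Bcat1 (16.6-fold), S100g (14.0-fold), Enpp3 (10.2-fold) and Wfdc2 (9.97-fold). Among epithelial defence genes all 4 listed members were called higher, Lcn2 by 17.0-fold (7.70 to 46.7) and Ltf, which encodes lactoferrin, by 6.43-fold (4.33 to 9.96).

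Genes higher in WT stroma included Igfbp3 (9.52-fold, 7.92 to 11.5), Cxcl12 (7.92-fold, 6.79 to 9.26), the long noncoding RNA Malat1 (6.31-fold) and the matrix proteoglycan gene Dcn (4.37-fold, 4.18 to 4.58). Of 24 endometrial stroma markers 12 were called higher in stroma (adjusted p = 0.00246), as were 12 of 15 smooth muscle genes (adjusted p = 3.19e-06), 6 of 8 blood endothelium genes (adjusted p = 0.00602) and 11 of 21 extracellular matrix genes (adjusted p = 0.00255), all by 2-sided Fisher exact tests. Among called members of these lists the exceptions in direction were Sox17 in the endothelium list and Lama5, a basement membrane laminin, in the matrix list, both called higher in epithelium. In the same exact tests the endothelium call was lost without low-level genes (adjusted p = 0.656), and the matrix call was lost at a threshold of 0.01 (adjusted p = 0.121) and with a minimum log2 fold of 1 (adjusted p = 0.0912). Among regulators, Dlx5 (6.74-fold) and Dlx6 (11.7-fold) were higher in epithelium, whereas Prrx1 (3.97-fold) and Tbx3 (2.81-fold) were higher in stroma. Of 9 Wnt genes 2 were called higher in epithelium, the receptor genes Fzd10 (10.3-fold) and Fzd6 (4.48-fold), and 4 higher in stroma, among them the antagonist Sfrp4 (14.3-fold) and the receptor genes Fzd1 (1.96-fold) and Fzd2 (1.91-fold). Hemoglobin transcripts were also higher in WT stroma, Hbb-bs by 11.8-fold (8.47 to 16.7).

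In KO uterus the same comparison called 271 of 2744 listed genes, 149 higher in epithelium and 122 higher in stroma. Of 24 simple epithelium markers 23 were called higher in epithelium (adjusted p = 7.94e-27, 2-sided Fisher exact test), and their summed level was 2.76-fold higher there. Calb1 was 9.06-fold higher in epithelium (5.74 to 15.1), S100g 6.71-fold (5.32 to 8.58), Wnt7a 4.99-fold (3.51 to 7.29) and Krt19 3.44-fold (2.96 to 4.00). Igfbp3 was 6.96-fold higher in stroma (6.02 to 8.08), Malat1 4.68-fold (4.36 to 5.03), Cxcl12 4.30-fold (3.65 to 5.08) and Dcn 2.51-fold (2.42 to 2.61). Called members higher in stroma numbered 7 of 14 in the smooth muscle list (adjusted p = 3.65e-05), 6 of 10 in the blood endothelium list (adjusted p = 4.93e-05) and 6 of 27 in the endometrial stroma list (adjusted p = 0.0159), by 2-sided Fisher exact tests. In the same exact tests the endometrial stroma call was lost at a threshold of 0.01 (adjusted p = 0.0663) and with a minimum log2 fold of 1 (adjusted p = 0.526).

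The compartment contrasts of the genotypes shared their direction and differed in size. Over 1737 genes listed in both tables, 486 were called in WT, 211 in KO and 208 in both. All 208 had the same direction (Fisher exact test of sign agreement, p = 5.59e-62). Naming spots by compartment in both genotypes would itself bring such agreement and overlap. The test also takes genes as independent, so its p measures no spread between animals. Independent lists would share 14.5 genes called higher in epithelium, where 109 were seen, and 14.9 called higher in stroma, where 99 were seen. Of the genes called in WT, 278 were not called in KO, and 3 had the opposite sign there. The median log2 contrast of the WT-called genes was 1.32 in WT and 0.78 in KO. Genes called in KO, a choice that favours large values in KO, still had a median of 1.20 in KO and 1.97 in WT, and 200 of these 211 had the smaller contrast in KO. Krt19 shows the pattern, at 8.91-fold in WT and 3.44-fold in KO. The gene-level difference between these contrasts was not tested.

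**Figure D3:**
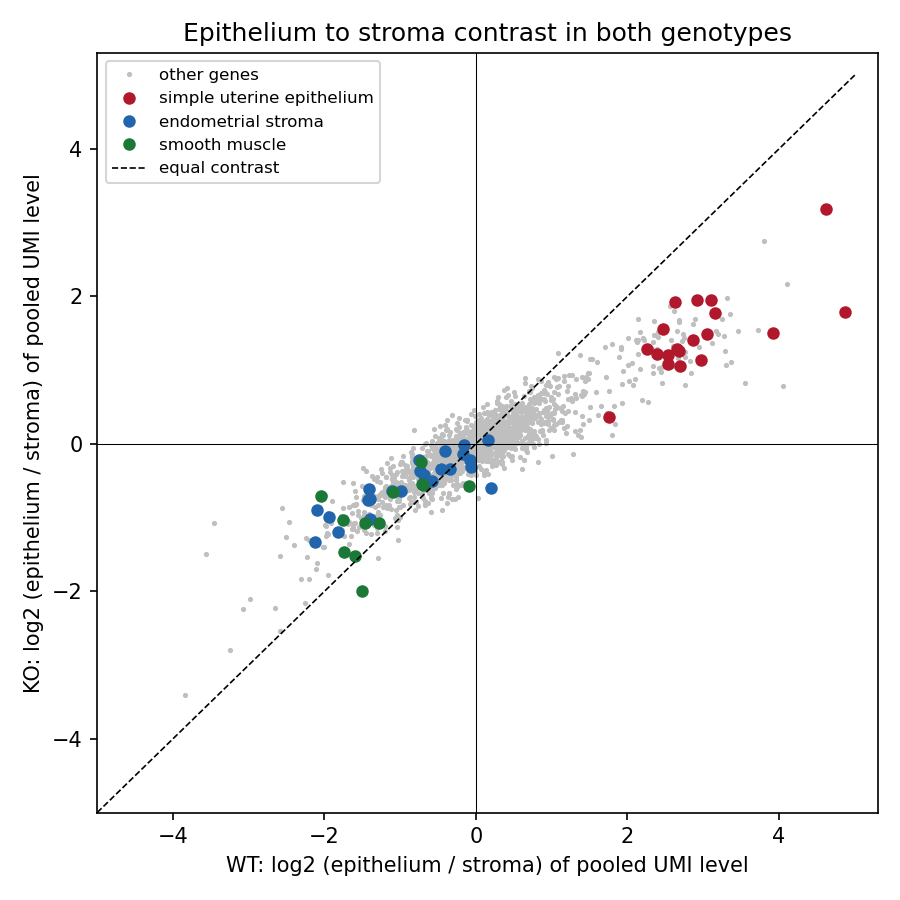
Each point is a gene listed in both compartment tables, with the log2 ratio of epithelium over stroma in WT on the horizontal axis and in KO on the vertical axis, and the dashed line marks equal contrast. Simple epithelium markers (red) lie below the line, with medians of 2.69 in WT and 1.41 in KO over the 19 members listed in both.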

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

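Folds centred on the median gene were chosen after the data were seen; the other alternatives were fixed earlier. At an adjusted p of 0.01 the called genes numbered 2 between genotypes in epithelium, 10 between genotypes in stroma and 175 between compartments in KO, list tests past adjustment fell from 17 to 11, and 0 genes were called in both genotype comparisons. Without the lowest 25% of genes by level, which drops called genes by construction, 9 genes were called between genotypes in stroma and 327 between compartments in WT, and 138 were called in both compartment comparisons. Other counts stayed within 1.5 times the main count. Of 157 named and called gene results, 34 lost the call at 0.01 and 14 at a minimum log2 fold of 1. These settings change calls only and cannot change a direction. Centring moved none of 165 gene values outside its counting interval. It turned the sign of 3 small list medians, among them proliferation genes in epithelium, from -0.08 to 0.02. No paired analysis was possible because the tables pool the animals of a genotype, and leaving out each replicate was not run for the same reason. Depth may limit all comparisons, with a median of 95 to 241 UMIs per listed gene and group, which was not tested.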

Other observations

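Many gene groups without a called member had medians in KO epithelium away from those of random lists matched on level. Among them were the retinoid and Wnt lists, each above 99.96% of random lists. Random draws ignore that genes vary together, and there is 1 pool per genotype. The percentiles thus describe the pools and are no test between animals. All 13 listed interferon-response genes were higher in KO epithelium, with a median log2 ratio of 0.53, above 100% of random lists; in stroma 4 of 7 were higher, with a median above 86.8%. Macrophage and antigen presentation genes had a median of 0.45 in epithelium, above 100% of random lists but 0.28 over the 8 members with an average above 1 in WT, and 0.26 in stroma, above 93.2%. Some lists not of epithelium stood higher in KO epithelium as well. Medians were 0.60 for endometrial stroma, 0.45 for extracellular matrix and 0.25 for blood endothelium (above 99.8% of random lists). The stroma and matrix lists share collagen genes and are not separate evidence. Smooth muscle genes went the other way, with a median of -0.32, above 0.11% of random lists. B2m, the light chain of MHC class I, had a log2 ratio of 0.68 in epithelium and -0.10 in stroma, and was itself called higher in WT stroma than in WT epithelium (1.77-fold). All 10 mitochondrially encoded genes were higher in KO epithelium (median 0.55, above 100% of random lists) and 8 of 10 in KO stroma (median 0.32, above 99.7%), with mt-Co1 at 1.54-fold in epithelium and 1.90-fold in stroma. Cytoplasmic ribosomal protein genes had medians of 0.08 in epithelium (above 99.6% of random lists) and 0.12 in stroma (above 50.8%). No member of these lists was called in epithelium. In stroma the called members were Fbln1 among the endometrial stroma markers and the 5 smooth muscle genes given above. B2m and mt-Co1 were picked after their values were seen.

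Among single genes picked after their values were seen and not called between genotypes, the clock gene Per2 had 24 UMIs in KO epithelium and 72 in WT (3.25-fold lower, counting interval 2.02 to 5.40). Nr1d1, another clock gene, was 1.81-fold lower in KO epithelium and 2.25-fold lower in KO stroma. The 2 listed lymphocyte and granulocyte genes, Jchain and Igkc, had a median log2 ratio of 0.78 in epithelium and -0.63 in stroma, with no call. Ighg2c, also picked after its value was seen, had 2 UMIs in KO stroma and 111 in WT stroma, with an adjusted p of 0.177 in the authors' deposited table. Hemoglobin transcripts had a median log2 ratio of -1.42 in stroma over 3 genes, and Hbb-bs, the 1 listed in epithelium, had 0.73 there (79 UMIs in KO and 44 in WT).

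All tests of explanations below were chosen after the results were seen. The epithelium to stroma contrast was smaller in KO for all 19 simple epithelium markers listed in both compartment tables, by a median log2 of -1.40, and for 20 of 24 endometrial stroma markers, with medians of -0.71 in WT and -0.52 in KO. A lack of depth in KO is argued against, since the KO pools were deeper than the WT pools in both compartments and 17 of the 19 KO intervals lay below the WT interval. Stroma within the KO epithelium spots stays open. Of the 24 stroma markers, 15 had intervals that left out their median share of 35.4%, and shares ran from -135% to 97.5%. Differences between genes or animals, which counting intervals do not hold, would do the same, a reading settled after the count was seen. Of the 4 genes called higher in KO epithelium, Igfbp5 would need 26.8% and Dio2 54.8%. Asb4 and Cxcl14 would need 166% and 192%, with lower bounds of 122% and 164%. That is more than a mixture of the pooled profiles can give, by counting error only. A share of the KO epithelium profile within the KO stroma spots is a candidate explanation. The markers need a median of 26.9%. For 6 of the 19 the interval left that out, Calb1 among them at 3.54% (upper bound 11.3%). A simulation of 177 genes mixed WT epithelium into WT stroma at a set share of 0.2, with counting error alone. There 91.0% of intervals covered the set share. The markers were held against their own median share, so the simulation is no direct yardstick for them. The 19 epithelium markers were all higher in KO stroma than in WT stroma, with a median log2 ratio of 1.14. Over the 31 listed in epithelium, the median of KO over WT was -0.20. Stroma within the KO epithelium spots would not raise markers in KO stroma. These values thus argue against it as the main source of the smaller contrast of the epithelium markers. For them, epithelium within the KO stroma spots and an effect of genotype on the cells cannot be told apart here without spot positions. For the stroma markers, mixture in either direction and genotype cannot be told apart.

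The 9 genes called higher in KO stroma may carry the same mixture. Against epithelium in the KO stroma spots, for genes above the KO epithelium level, stand 3 of the 9, Bpifb5, Col6a4 and Dio2. The share each needed had a lower bound above 100%. These bounds hold counting error only and not differences between animals. They take the pooled profile of spots named epithelium as the source, and epithelium of another profile was not tested. Such a mixture, that is epithelium in the KO stroma spots, for the other called genes would need shares of 34.1% to 65.7%, and for 5 of these 6 the interval lay above the median share of the markers. Measured against the highest marker share, 47.1% for Atp1b1, a choice tried as well, 4 of the 9 intervals lay above it. That share is imprecise, with an interval from -20.0% to 100.7%. Since called genes were picked for large values, mixture and genotype cannot be told apart for these 6, and an effect of Ezh2 deletion remains open and untested for all 9.

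Lower smooth muscle transcripts in KO stroma may reflect less muscle tissue among the spots named stroma. All 9 members of the list that were not called were lower as well, which that explanation needs, and so were all 6 of these with an average above 1 in KO stroma, whose listing does not rest on WT. Scaling to the UMI total would lower other stromal genes as much, but the endometrial stroma list had a median of 0.11 and a lower quartile of -0.23, against a median of -0.97 for the muscle list. A lower level of contractile transcripts within the cells, as an effect of genotype, stays open and was not tested.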
